A study of Mus musculus with 2 samples.

How the data were processed

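Total liver RNA of HFHS-fed WT and CREBH-Tg mice was measured on 2 one-colour Agilent arrays, 1 per pooled genotype sample, on 1 slide. Per the labels, RNA was extracted with Trizol, amplified and labelled with Cy3 as cRNA. Per the file headers, the arrays were read with Agilent Feature Extraction 10.10.1.1, and their probe annotation lies on the mouse build mm9. The deposited processed signal is an intensity on a linear scale, background-subtracted and detrended within each array and not scaled between arrays, per the file headers. The deposited median spot signal and median local background are raw intensities. The authors' value table holds intensity as well: each column equalled the processed signal times 1 constant per array, 2.59 for WT and 2.68 for CREBH-Tg. Its medians were 89.8 and 81.0, and the rule behind the constants is not given in the sources used here. Groups were taken from the labels, and the number of animals per pool is not given there.

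For the main values, the log2 of the processed signal was taken and each array's 75th percentile subtracted. Control spots and 300 spots marked as outliers on either array were left out, and spots of 1 probe were averaged on the log2 scale. A probe counted as detected when over 50% of its spots were well above background. A gene's value was that of its brightest probe detected on both arrays, and 2-fold was the threshold of size. Of 3376 genes with more than 1 measured probe, the median range of log2 ratios over the probes was 0.13. Of the genes 2-fold apart, 27 had more than 1 measured probe, and in 21 of them every probe lay on the same side of 0. Probes were named by matching their transcript accessions, without versions, to a RefSeq gene table of the GRCm38.p6 assembly, used for names only. This named 27233 of 55677 probes, for 20660 genes. The other 28444 probes were left unnamed.

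No test across genes was run, because each genotype has 1 array. The error given is the SD of single-spot log2 ratios of 276 probes spotted at least 5 times, computed in 3 signal classes. Its 95% range, 1.96 SD, was 0.40, 0.17 and 0.094 from the dimmest to the brightest class. The number of arrays limits the precision of all values. A total of 30 gene lists were fixed before the data were examined, with all settings except those named as added. The median log2 ratio of each list was set against 10000 random lists of the same size drawn from 50 signal classes, as a description of these arrays. Where a gene was detected on 1 array only, the bound is its signal over the higher of the lowest signal well above background on the other array and the dim probe's own signal there.

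The genes named were Creb3l3, the 10 highest and 10 lowest log2 ratios apart from predicted genes and clones, and the 3 greatest bounds on each side. All CREBH-linked genes were named, and in each other list up to 4 members at least 2-fold apart or, with none, the member farthest from 0. Sex chromosome genes were named as a check. Some genes that the rule names are not reported here. Genes outside this rule are said to have been chosen after their values were seen, and Fga, Fgb and Fgg were as well. The gene summary and list steps were tested on simulated data for the comparison of CREBH-Tg with WT over 13881 genes. All 100 genes changed by a log2 ratio of 1.5 and all 100 changed by 2.5 were called, and 0 of 13681 unchanged genes. The simulated noise was spot noise alone, which is small beside the 2-fold threshold, so this outcome was largely fixed in advance. It checks the steps and gives no rate of false calls between animals, pools, labelling reactions or hybridisations. Of 200 unchanged lists, 6 lay outside the middle 95%.

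The alternatives were scaling by the median, by the 75th percentile over detected probes, by quantile normalization or by loess with a span of 0.3, the authors' value table, the mean over a gene's probes, no filter or a stricter filter on dim probes, and thresholds of 1.5-fold and 3-fold. Normexp background correction with an offset of 50 was planned on the mean spot signal. The files read here hold the median spot signal instead, so it was run on that, as an alternative added after the files were read. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.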

Results

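Liver transcripts were compared between wild-type (WT) mice of the C57B6J strain and CREBH-Tg mice, which carry a human cDNA of the active form of CREBH and express it mainly in the liver. CREBH, encoded by Creb3l3, is a liver-enriched transcription factor known to act on genes of lipid metabolism and the acute phase response. Both genotypes had been fed the HFHS diet for 12 weeks. Liver RNA was pooled by genotype, and each pool was labelled with Cy3 and hybridised to 1 Agilent mouse array. The number of mice in each pool is not given in the sources used here. With 1 array per genotype there were no replicates, so no difference below was tested against the spread between animals or pools, and all are described by size alone.

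Each array held 59305 non-control spots for 55681 probes. Of these spots, 55.41% were well above background on the WT array and 58.34% on the CREBH-Tg array, and none was saturated. The 75th percentile of processed intensity was 333 on the WT array and 309 on the CREBH-Tg array. A total of 13881 named genes were well above background on both arrays, and their log2 signals correlated across genes with r = 0.99, where genes are not independent replicates. Probes spotted repeatedly gave the only measure of error. The SD of single-spot log2 ratios was 0.20 in the dimmest of 3 equal classes of genes by signal, 0.085 in the middle class and 0.048 in the brightest. This spot noise leaves out variation between animals, pools, labelling reactions and hybridisations.

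The mouse Creb3l3 transcript differed by a log2 ratio of -0.0053 between the arrays, with log2 signals of 6.97 in WT and 6.97 in CREBH-Tg relative to the 75th percentile. The transgene is human cDNA, so the mouse probe does not check the genotype labels. The Y-linked genes Ddx3y and Eif2s3y were well above background on both arrays, at log2 ratios of -0.25 and -0.22, and Uty at 0.084. The probes for Xist and Kdm5d were not well above background on either array.

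Of the 13881 genes, 92 were at least 2-fold higher and 93 at least 2-fold lower in CREBH-Tg than in WT liver, together 1.33%. The higher genes that were also bright included Cidec, a lipid droplet protein, the hormone Fgf21, the apolipoprotein Apoa4 and the acute phase proteins Lcn2, Saa1 and Saa2. The bright genes that were lower included the melanogenesis enzyme Dct and the cytochrome P450 genes Cyp4a12a and Cyp4a12b. Most of the 185 genes were dim: 138 lay in the dimmest class, 27 in the middle class and 20 in the brightest. In the brighter 50% of genes, 21 were higher and 8 lower. The counts depended on the processing: normexp run on the median spot signal left 42 higher and 16 lower, and a stricter filter on dim probes 29 and 11. The offset of 50 added in normexp shrinks the log2 ratios of dim genes by construction. Of the 2-fold calls, 49.7% were higher, and scaling to the median in place of the 75th percentile made that 59.9%.

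**Figure D1:**
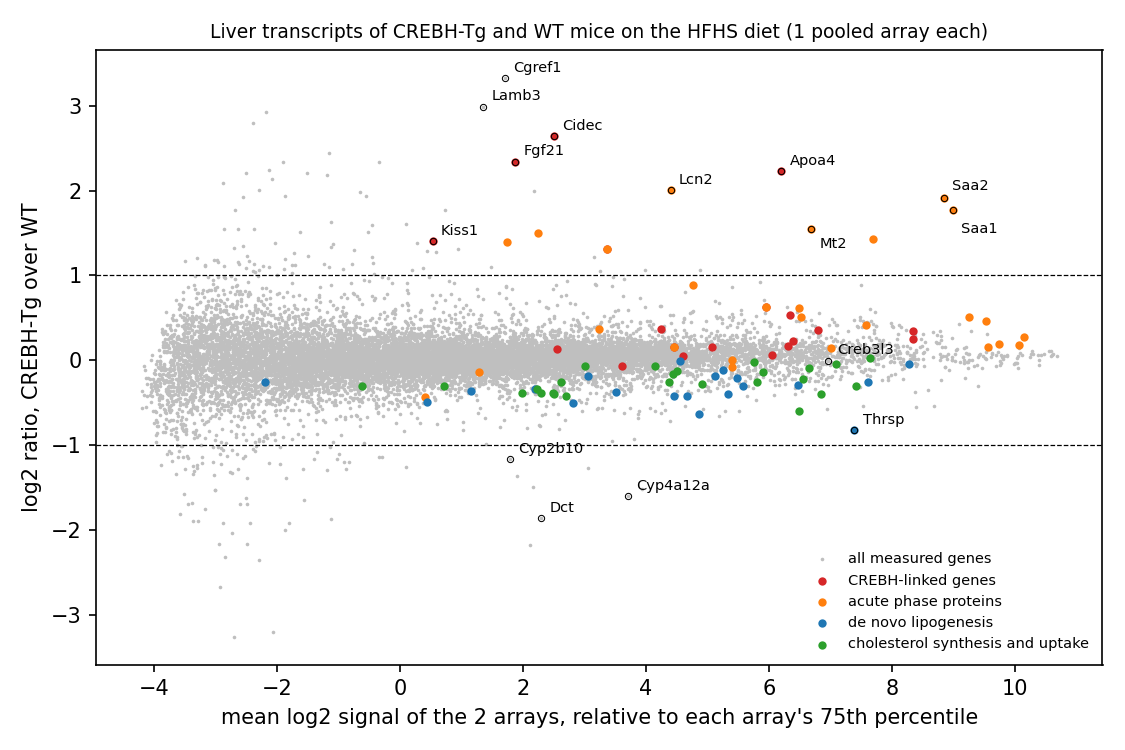
Log2 ratio of CREBH-Tg over WT against the mean log2 signal of both arrays relative to each array's 75th percentile, with 1 point per gene for 13881 genes and dashed lines at 2-fold. Colours mark 4 gene lists fixed in advance, and ringed points are named. Cidec, Fgf21, Apoa4, Lcn2, Saa1 and Saa2 lie above the upper line at middle to high signal, while most of the 185 genes beyond the lines lie at low signal.

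Genes linked to CREBH in earlier work were higher in CREBH-Tg liver as a list. The median log2 ratio of the 19 measured genes was 0.35, above all 10000 random lists matched on signal, and 18 of the 19 lay above 0 (16 to 19 over the scalings tried). Cidec was 6.24-fold higher, Fgf21 5.07-fold and Apoa4 4.69-fold. Kiss1, which encodes the peptide kisspeptin, was 2.65-fold higher, and Apcs, serum amyloid P, 2.48-fold. None of the 19 was 2-fold lower. The next genes were Hamp, the iron hormone hepcidin, at 1.54-fold, and the fatty acid elongase Elovl2 at 1.44-fold. Apoa5 was 1.29-fold higher, Bdh1 1.28-fold and Apoa1 1.27-fold. The gluconeogenic genes Pck1 and G6pc were 1.19-fold and 1.17-fold higher, Elovl5 1.13-fold, Fads1 1.12-fold and Crp 1.12-fold, and Fads2 had a log2 ratio of 0.13. Log2 ratios of Ppara (0.061), Insig2 (0.047) and Gpihbp1 (-0.067) were within the 95% range of spot noise, 0.094 in the brightest class. Of these genes, Cidec, Kiss1, Bdh1, Ppara and Insig2 had more than 1 measured probe, and the probes of Ppara went both ways.

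The list of acute phase proteins, many of which the liver secretes in inflammation, had the highest median. The median log2 ratio of 26 genes was 0.48, above all 10000 random lists, with 8 at least 2-fold higher and none 2-fold lower. Lcn2 was 4.02-fold higher, Saa2 3.75-fold, Saa1 3.41-fold and the metallothionein Mt2 2.91-fold. The other 4 were Orm3, Mt1, Saa3 and Apcs, named after their values were seen, at 2.83-fold, 2.68-fold, 2.63-fold and 2.48-fold. Fibrinogen chains were nearer to equal, with log2 ratios of 0.0069 for Fga, 0.16 for Fgb and 0.19 for Fgg. Saa1 and Saa2, the Orm genes and the metallothioneins are near-identical families whose probes can cross-hybridise, so their separate values are uncertain. Apcs, Crp and Hamp stand in this list and in the CREBH-linked list. Immune cell markers beside it went both ways, with a median log2 ratio of 0.27 for lymphocyte markers and -0.068 for macrophage markers.

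Genes of fatty acid and cholesterol synthesis were lower in CREBH-Tg liver as lists, by less than 2-fold each. For de novo lipogenesis the median log2 ratio was -0.32, below all 10000 random lists, and 20 of 20 genes lay below 0 (18 to 20 over the scalings tried). Of these, 17 were lower by more than the 95% range of spot noise. That range leaves out differences between pools, and of 15 housekeeping genes 5 lay above it and 2 below. Thrsp, a regulator of lipogenesis, was 1.76-fold lower and fatty acid synthase (Fasn) 1.42-fold. For cholesterol synthesis and uptake the median was -0.26, also below all 10000 random lists, with 24 of 25 genes below 0 (19 to 25 over the scalings). Msmo1, an enzyme of sterol demethylation, was 1.51-fold lower. Hmgcs1, an enzyme of the mevalonate pathway, was 1.31-fold lower. Fasn and Hmgcs1 were named after their values were seen. Among clock genes, Arntl was 2.17-fold higher (log2 ratio 0.66 under normexp) and the list median was -0.062, at percentile 3.73.

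**Figure D2:**
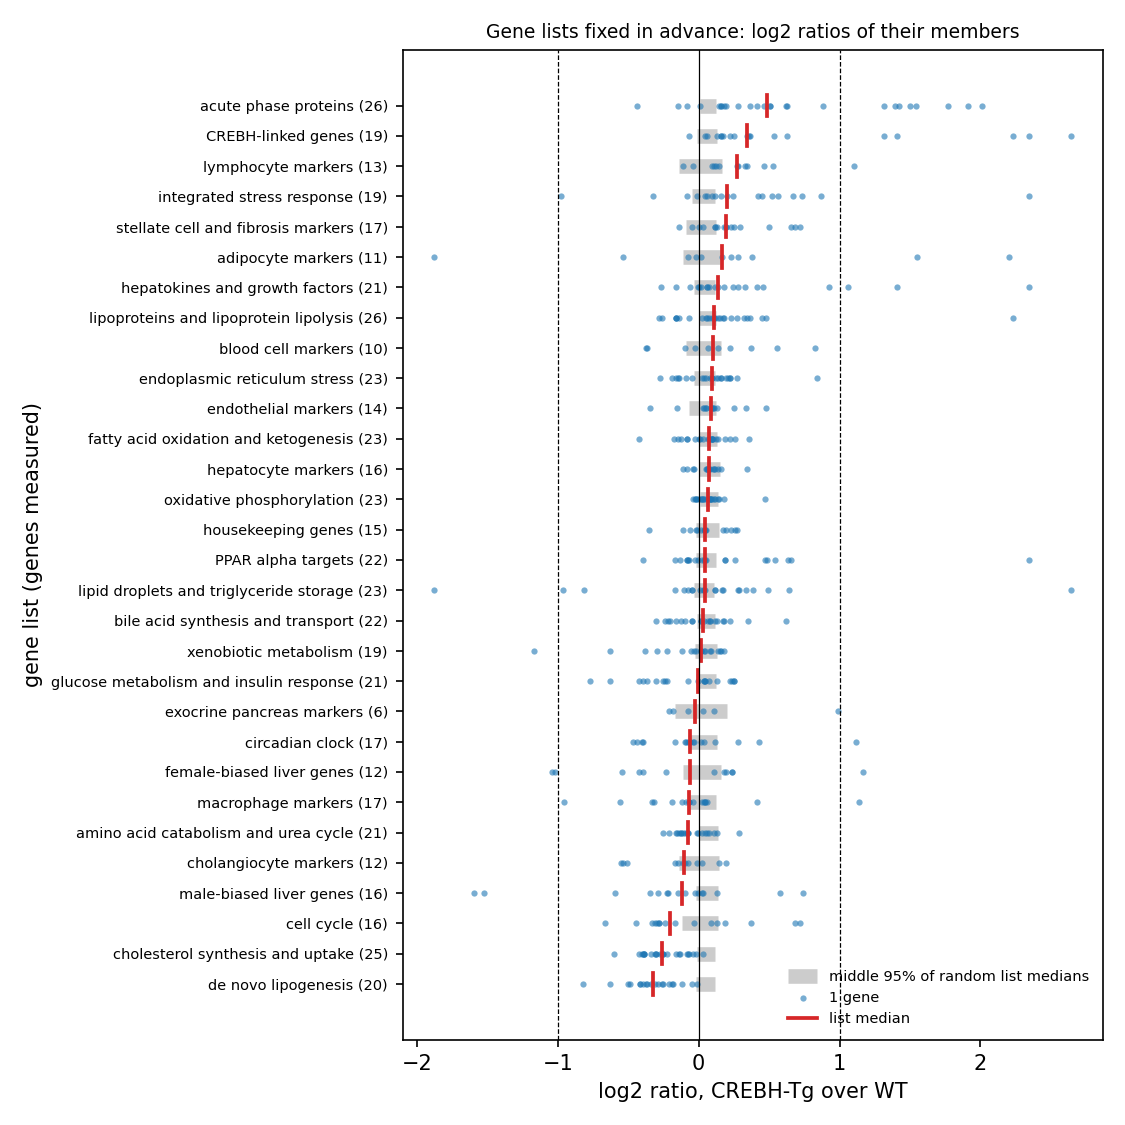
Log2 ratios of CREBH-Tg over WT for the members of 30 gene lists fixed in advance. Each point is 1 gene, the red bar is the list median, the grey bar covers the middle 95% of medians of signal-matched random lists, and dashed lines mark 2-fold. Acute phase proteins have the highest median (0.48) and de novo lipogenesis the lowest (-0.32).

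Most other lists of metabolism had medians within the middle 95% of random lists. The median log2 ratio was 0.076 for fatty acid oxidation and ketogenesis (percentile 59.2), where Ppargc1a was 1.34-fold lower, and 0.043 for PPAR alpha targets (percentile 41.1). Fgf21 was the 1 gene of 22 in the latter list that reached 2-fold. Lipoproteins and lipolysis had a median of 0.11 (percentile 95.1), where Apoa4 alone was 2-fold apart. In the lipid droplet list (median 0.042, percentile 54.8, and 0.11 at percentile 98.5 with the mean over a gene's probes), Cidec was 6.24-fold higher and Cidea, of the same gene family, 3.67-fold lower. Cidea was dim. Glucose metabolism had a median of -0.0030 (percentile 5.08, and 0.185 under quantile normalization), with Pfkfb3 1.71-fold lower. Bile acid synthesis and transport had 0.027 (percentile 18.5), with the transporter Slco1a4 1.54-fold higher. Oxidative phosphorylation had 0.064 (percentile 34.2), with Atp5o 1.39-fold higher. Xenobiotic metabolism had 0.013 (percentile 16.1), with Cyp2b10 2.25-fold lower. Amino acid catabolism and the urea cycle had a median of -0.076, below the middle 95% at percentile 0.010, with Bcat2 farthest from 0 at 0.29. Median scaling, which adds the same amount to every gene, put that median at 0.014 and left its percentile at 0.010.

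Among stress and hormone lists, the integrated stress response had a median log2 ratio of 0.20 (percentile 99.98). Fgf21 alone of the 19 genes measured on both arrays reached 2-fold. Mthfd2, a member well above background on the CREBH-Tg array only, had an approximate bound of 2.26-fold higher. Endoplasmic reticulum stress genes had a median of 0.092 (percentile 90.5), and Sdf2l1, a chaperone component, was 1.79-fold higher. Hepatokines and growth factors had a median of 0.14 (percentile 99.2, and 94.0 under normexp), and 3 of 21 genes were at least 2-fold higher. These were Fgf21, Kiss1 and Enho, which encodes adropin and was 2.09-fold higher. Enho was just under 2-fold under quantile normalization, at a log2 ratio of 0.998. Fgf21 belongs to 4 of the lists. Cell cycle genes had a median of -0.20 (percentile 0.060), although the gene farthest from 0, Mcm2, was 1.65-fold higher. Of its 16 genes, 11 were in the dimmest class, and its median was -0.054 (percentile 4.51) under normexp.

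Genes with a known sex bias in liver and other cell types were listed to describe the pools. Male-biased genes had a median log2 ratio of -0.12 (percentile 0.010), with Cyp4a12a 3.03-fold and Cyp4a12b 2.87-fold lower. These are near-identical genes whose probes can cross-hybridise. Female-biased genes had a median of -0.065 (percentile 8.47), with Cyp3a44 2.25-fold higher and Cyp2b9 and Cyp2b13 2.06-fold and 2.03-fold lower, all dim. None of the 3 was 2-fold apart under normexp, at log2 ratios of 0.41, -0.41 and -0.38, and Cyp2b9 and Cyp2b13 were not under median scaling or quantile normalization either. The female-biased median was 0.11 with no filter on dim probes. Stellate cell and fibrosis markers had a median of 0.19 (percentile 99.94) with no gene at 2-fold and the proteoglycan Lum 1.65-fold higher. The median was 0.27 for lymphocyte markers (percentile 99.92), with Cd3d 2.14-fold higher, and -0.068 for macrophage markers (percentile 1.75), with Trem2 2.20-fold higher. Median scaling put the macrophage median at 0.021, again at percentile 1.75, and normexp at -0.034 (percentile 5.75). Trem2 and Cd3d, both dim, were at log2 ratios of 0.70 and 0.61 under normexp. Adipocyte markers had a median of 0.17 (percentile 98.7), or 0.086 (percentile 89.0) under normexp. Adipoq was 4.61-fold and Retn 2.93-fold higher and Cidea 3.67-fold lower. These 3 genes were dim, and their log2 ratios were 0.99, 0.79 and -1.14 under normexp against 2.20, 1.55 and -1.88 in the main values.

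The remaining cell type and control lists lay within the middle 95% of random lists. Their medians were 0.071 for hepatocyte markers (percentile 51.3), with Apoa1 at 0.35, and 0.089 for endothelial markers (percentile 89.6), with the dim Emcn at 0.48. They were -0.10 for cholangiocyte markers (percentile 6.73), with Krt23 at -0.55, and 0.10 for blood cell markers (percentile 88.1), with the dim Ppbp at 0.82. Exocrine pancreas markers had a median of -0.024 (percentile 31.6), with the dim Cela1 at 0.99. Housekeeping genes had a median of 0.044 (percentile 32.4). In all, 13 of the 30 lists lay outside the middle 95%, against 1.5 by chance in lists of unrelated genes.

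The 10 genes with the highest log2 ratios were Cgref1 (3.33), the laminin chain Lamb3 (2.99), the keratin Krt20 (2.93), S100g (2.80), Cidec (2.64), Calml4 (2.45), Olfr586 (2.34), Fgf21 (2.34), Bcl2l14 (2.33) and Agap2 (2.25). Krt20, S100g, Calml4, Olfr586 and Agap2 were in the dimmest class. Among the 10 lowest were Cfap161 (-3.26), Tgif2lx2 (-3.20), Fam161a (-2.68), Zfp979 (-2.35), Troap (-2.32), Olfr746 (-2.16), Fam120c (-2.16), Hif3a (-2.04) and Moxd1 (-2.00). These genes were all in the dimmest class. Hif3a had a second probe at 0.27. Under normexp on the median spot signal Fam161a, Troap, Olfr746, Fam120c and Hif3a were no longer 2-fold apart. The other dim genes named here stayed so at smaller log2 ratios, 1.09 to 1.70 for the higher and -1.08 to -1.66 for the lower. Olfactory receptor genes form a large family of similar sequences, so the values of Olfr586 and Olfr746 are uncertain. In the brighter 50% of genes, a group chosen after the values were seen, the highest also included Tmem86a, 3.99-fold higher. Among the lowest there were Dct (-1.86), Cyp4a12a (-1.60), Cyp4a12b (-1.52), Nat8f5 (-1.49), Lrtm1 (-1.36), Ces2b (-1.27) and Cyp2b10 (-1.17).

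Some genes were well above background on 1 array only and have a bound in place of a ratio, set against the lowest signal well above background. On the CREBH-Tg array alone 762 genes were measured, 53 of them at least 2-fold higher, and on the WT array alone 245, of which 148 were at least 2-fold lower in CREBH-Tg. That lowest signal was lower on the CREBH-Tg array, at a log2 signal of -4.55 against -4.13, so these counts are not balanced. It is not a strict detection limit, since some probes not well above background lay higher, such as that of Ncam1 at -3.74 in WT. These counts and the bounds below are therefore approximate. By this rule Dnah2, a ciliary dynein chain, was at least 57.3-fold higher, Fam183b at least 29.4-fold and Tmem45b at least 23.8-fold. Faiml was at least 12.2-fold lower, Cerox1 at least 7.71-fold and Slc24a4 at least 7.53-fold.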

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

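The tests of macrophages, of lymphocytes and of time of day were chosen after the values they weigh were seen. The requirement on markers above background in the tissue tests was likewise added after their counts were seen.

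Probes that could not be named were not part of the gene comparisons, and some of them differed between the arrays. Of 11442 unnamed probes well above background on both arrays, 52 were at least 2-fold higher and 165 at least 2-fold lower in CREBH-Tg. Among those brighter than the median of all probes well above background on both arrays, named or not, the counts were 13 and 15. The highest there lay in the regions given by the files on mm9 as chromosome 19, 5771425 to 5848475, at 5.72-fold higher, and chromosome 1, 175660642 to 175671878, at 5.59-fold higher. The lowest lay on chromosome 13, 70745306 to 70837331, at 4.11-fold lower, and chromosome 5, 14943275 to 14944205, at 3.38-fold lower.

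Acute phase genes were higher in the CREBH-Tg pool, with a median log2 ratio of 0.48. A rise in macrophages as large as the acute phase median is argued against by 17 macrophage markers. Their median was -0.068 (95% interval from a bootstrap over genes -0.19 to 0.044). Such intervals do not cover the spread between pools. A smaller rise, or active macrophages without more of them, was not tested. More lymphocytes stay open, since their 13 markers had a median of 0.27 (0.11 to 0.34) and 9 of them were in the dimmest class. Signal-matched random lists argue against a signal-dependent bias between the arrays, since the middle 95% of their medians ran from 0.0094 to 0.12. After loess 8 of 8 genes stayed at least 2-fold higher. Their log2 ratios were 1.31 or more beforehand, so a bias of that size could hardly have changed this. For a cytokine response at the time of sampling, 18 cytokine response genes had a median of 0.037 (interval -0.13 to 0.20, percentile 56.8). This argues against a broad rise in these genes as large as the acute phase median. A weaker response stays open, and an earlier response was not tested. An effect of the transgene and a difference between the animals pooled both remain open, because each genotype is 1 pool.

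Lipogenic and cholesterol synthesis genes were lower as lists in the CREBH-Tg pool. Signal-matched random lists argue against a signal-dependent bias between the arrays. The middle 95% of their medians ran from -0.017 to 0.12 for lipogenesis, whose median was -0.32. For cholesterol synthesis it ran from -0.013 to 0.11, against a list median of -0.26. After loess the list medians were -0.37 and -0.31, the latter being the higher of both. Loess removes a trend with signal that the matched lists already share, so this outcome adds little. Another time of day at sampling cannot be told apart from an effect of genotype: clock genes in phase with Arntl exceeded those in antiphase by 0.35 in median log2 ratio, with a 95% interval of 0.11 to 1.19 from 4 and 11 genes, which holds the 0.5 set as the deciding size. Feeding state and differences between the pooled animals were not tested and stay open beside the transgene.

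Some adipocyte and epithelial genes, Adipoq, Retn, Krt20 and Lamb3, were higher in the CREBH-Tg pool, while Cidea (-1.88) and Car3 (-0.54, chosen after its value was seen) were lower and cholangiocyte markers had a median of -0.10. Fat tissue in the pool was tested on 13 further adipocyte markers, of which 1 was at least 1.5-fold higher (exact 95% interval of the share 0.195 to 36.0%), and intestinal or gallbladder tissue on 19 further markers, of which 1 was (0.133 to 26.0%). As written beforehand, with an upper limit under 50%, both results counted against these tissues. That reading was withdrawn only under a requirement added after the counts were seen, that 80% of markers be above background on the CREBH-Tg array. There, 7 of the 13 and 11 of the 19 markers were, and the others were too dim to show a small rise. Gpd1 and Car3, at log2 signals of 7.07 and 8.96 in WT liver, would hide a small share of fat. Under the added requirement, traces of either tissue cannot be told apart from expression in the liver itself.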

How the results depend on the processing

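The normexp version was chosen after the files were read, and the planned version on mean spot signal was not run. No paired analysis was possible because each genotype has 1 pooled array and no test was made. The counts of genes at least 2-fold higher and lower, 92 and 93, were 42 and 16 under normexp, 605 and 782 with no filter on dim probes and 29 and 11 with the stricter filter, which tested 8751 genes in place of 13881. They were 321 and 310 at 1.5-fold and 30 and 26 at 3-fold. Under normexp 56 of the 185 genes kept their call. The offset of 50 shrinks dim ratios by construction. Effects of the other input signal and background correction were not tested. With no filter 184 kept theirs and 1 turned. The share of higher calls, 49.7%, was 59.9% under median scaling (115 and 77 genes), 72.4% under normexp and 72.5% with the stricter filter. No scaling moved the median of all genes by over 0.1, the farthest being 0.090 under median scaling.

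Of 267 alternative list medians, 264 moved by less than 0.13, the SD of single-spot log2 ratios over all signals, which is a measure of size here and not the error of a list median. Median scaling, the 75th percentile over detected probes and the authors' value table add nearly 1 amount to every gene (0.090, -0.026 and -0.060). Under these, no median could move by 0.13 and percentiles could hardly change, so they do not test stability. The sign turned in 28 alternatives of lists within the middle 95% of random lists, whose medians lie near 0, and in 2 of the 115 alternatives of the other lists. These were amino acid catabolism, from -0.076 to 0.014, and macrophage markers, from -0.068 to 0.021, both under median scaling, which adds 0.090 to every gene and left their percentiles at 0.010 and 1.75. In 8 of the 115 the list came within the middle 95%: cell cycle under normexp, hepatokines under normexp and the stricter filter, macrophage markers under normexp and with no filter, and adipocyte markers under normexp, quantile normalization and loess. Glucose metabolism and clock genes lay outside it under normexp, quantile normalization and loess, clock genes and lipoproteins (percentile 97.52) with the stricter filter, and lipid droplets with the mean over a gene's probes. The cell cycle median moved from -0.20 to -0.054 under normexp, and female-biased genes from -0.065 to 0.11 with no filter and 0.15 with the stricter one, over 17 and 6 genes in place of 12. In every alternative that changes values, CREBH-linked genes had 5 and acute phase proteins 8 members at least 2-fold higher. The CREBH-linked median ranged from 0.25 to 0.44 over the scalings, lipogenesis from -0.38 to -0.23 and cholesterol synthesis from -0.32 to -0.17. Of 45 named genes at least 2-fold apart, none turned, and 362 of 382 alternative values stayed 2-fold apart. Of those lost under normexp, Adipoq was at 0.99, Retn 0.79, Trem2 0.70, Arntl 0.66, Cd3d 0.61, Cyp3a44 0.41, Cyp2b9 -0.41 and Cyp2b13 -0.38. Signal over background limits these data: 138 of the 185 genes at least 2-fold apart lay in the dimmest class.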

Other observations

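Members of some gene families and pathways went in opposite directions, in examples picked after their values were seen. Cyp4a10, Cyp4a14 and Cyp4a31, omega-hydroxylases known as PPAR alpha targets, were 1.55-fold, 1.40-fold and 1.57-fold higher in CREBH-Tg liver, while Cyp4a12a was 3.03-fold lower. These genes are similar in sequence. In the integrated stress response list, Atf3 was 1.82-fold, Chac1 1.66-fold and Trib3 1.59-fold higher, while asparagine synthetase (Asns) was 1.97-fold lower. Among clock genes, Arntl was 2.17-fold higher, and Per1, Per2, Per3 and Ciart were 1.32-fold, 1.31-fold, 1.35-fold and 1.38-fold lower. Arntl, Per2 and Per3 were dim. Each of these directions was the same under all scalings tried, although those that add 1 small amount to every gene could not have turned them. Under normexp Arntl was at a log2 ratio of 0.66. Other clock genes in antiphase with Arntl did not follow in this way. Nr1d1 was 1.21-fold higher, and the rest had log2 ratios from -0.099 (Tef) to 0.017 (Nr1d2).

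Fibrosis markers were higher as a list without any gene at 2-fold, and the examples here were also picked after their values were seen. Beside Lum, Thbs2 was 1.60-fold, Timp1 1.58-fold and Acta2 1.42-fold higher, and the collagen gene Col1a1 1.22-fold. Thbs2 and Timp1 were in the dimmest class. Macrophage genes split, with Marco 1.94-fold lower and the dim Trem2 2.20-fold higher. Plin1 and Lep, which are abundant in fat, were well above background on the CREBH-Tg array only, with bounds on the log2 ratio of 0.59 and 0.31. These bounds are small and approximate. The Lep signal, -3.82 on the CREBH-Tg array, lay below some signals not counted as well above background on the WT array.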
